A study of Mus musculus with 12 samples.

How the data were processed

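The series followed the random differentiation of mouse embryonic stem (ES) cells, which can form every tissue of the embryo, by way of embryoid bodies (EB), aggregates in which ES cells differentiate without a directed signal. Per the labels, undifferentiated ES cells were grown on gelatin with leukemia inhibitory factor, and dissociated embryoid bodies were plated with serum for 4, 8, 15 or 21 days. Messenger RNA was measured on 12 arrays with 2 channels each. Every array held ES RNA in 1 channel and EB RNA of 1 day in the other, and each day had 3 arrays. Groups and array numbers were taken from the sample titles, and no sample was left without a group. The labels do not say whether the arrays of a day came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

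Per the labels' protocols, total RNA was turned into double-stranded cDNA and transcribed in vitro with dye-labelled UTP. The deposited values, read as log2 ratios of the 2 channels, were normalized by the authors with a method not given in the sources used here. Base 2 is a convention that the labels do not settle, and deposited values reach 4.47 in size. The scanner, background correction, filter on dim spots and array design were likewise not given in the sources used here, and signal intensities were not used here. The value table held 11520 features on 12 arrays with 0 missing values. The column medians were 0.0017, -1.00e-04 and -0.0018 for the day 4 arrays 1 to 3, -9.00e-04, 0.0026 and 0.0034 for day 8, 0.0068, 0.00365 and 0.00475 for day 15, and 0.0106, 0.01035 and -0.0018 for day 21, so each array had been centred near 0. Precision is limited by the number of arrays.

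The direction of the deposited ratio is likely and not settled. Sample titles put ES before EB and the dye fields give Cy5 to ES RNA, whereas the label protocols give Cy3 to ES RNA and Cy5 to EB RNA. Before the data were examined, the plan was to read the value as ES over EB and to turn its sign. The values of marker genes with known behaviour went against that reading: ES cell genes such as Zfp42 and Nanog were negative and fetal liver and yolk sac genes such as Afp and Ttr strongly positive. All values are therefore printed with the deposited sign, positive meaning higher in EB, as the label protocols imply. This departs from the plan and opposes the titles and dye fields. Under the opposite reading every higher and lower in the text is exchanged, and no p-value or count of calls moves, since the tests were two-sided. No dye swap was made, so a dye effect of a gene stays in each ratio against ES, and drops out of differences between days only if it was alike on all arrays.

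Genes were named through GEO's platform annotation, which can be old. Of the features, 10043 had 1 gene symbol, 29 had several and 1448 had none. Symbols were looked up by Entrez ID in RefSeq's gene table of GRCm38.p6, where 10025 matched and 0 changed; no genome and no coordinates were used. Probes of a gene were averaged, which gave 9212 genes, and the 1477 features with several symbols or none were kept on their own, so 10689 features were tested. For 12 of the 754 genes with more than 1 probe, the probes differed by over 1 at day 21.

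Features were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on the values as deposited, in 1 model with a mean for each day over all 12 arrays, so that the 4 groups shared 1 estimate of the spread with 8 residual and 4.35 prior degrees of freedom. Each day was tested against 0. No ES sample was hybridised on its own, so the ES channel counts as 1 control sample, and this test leaves out the spread of the control. Days were compared by contrasts and by a moderated F-test of any difference between days. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 28 lists, and again with the correlation estimated for each list and with fry. The lists covered 713 different genes, of which 614 were measured, with 9 to 42 measured members each. The lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. That rule took, for each day against ES, the 8 genes with the largest positive and the 8 with the largest negative mean among called genes with 1 sign on all 3 arrays. Between days it took up to 5 genes each way with arrays that did not overlap. It added up to 4 members of each list with the largest absolute values and 22 marker genes, of which 21 were measured. Genes named outside it are said to have been chosen after their values were seen. Errors after ± are standard deviations over 3 arrays. Plots were drawn with matplotlib 3.10.9.

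The fits were tested on simulated arrays with the spread of each real feature, with 200 of 10689 features shifted. For day 21 against ES, 58.2% of shifts of 0.5, 94% of shifts of 1 and 100% of shifts of 2 were recovered, with 8 false calls. For day 21 against day 4 the shares were 22.4%, 88.1% and 98.5%, and for day 15 against day 8 they were 31.3%, 76.1% and 97%, with 8 false calls each. Each of the 3 list tests recovered 3 of 3 lists shifted by 0.3 at day 21 against ES and called 0 of the 25 others. Simulated genes were drawn independently, whereas the estimated correlation of real lists reached 0.537, for ribosomal proteins. The simulation therefore cannot show how often correlated genes give false list calls.

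The feature order repeated in 24 blocks of 480. In every block the same 6 positions had no gene in the annotation. At 4 of these positions, 96 features in all, the arrays fell into 2 sets. Their median lay between -1.54 and -1.04 on 5 arrays (day 4 array 3, day 8 arrays 2 and 3, day 15 array 3 and day 21 array 3) and between -0.31 and 0.064 on the other 7. These are called the second and the first array set; the labels give no batch. After removal of the day means, arrays of 1 set had a mean correlation of 0.0959 and arrays of different sets of -0.0935. The 96 features that define the sets entered these correlations, so their direction was partly built in. They cannot show that other features differ between the sets. Counts are also given with the array set as a term and within each set. The 96 features stayed among those tested, so such counts include any calls of them. Other alternatives were centring, quantile normalization and scaling of the arrays, each probe on its own, array weights, the replicate number as a block, a fit of the compared days alone, an unmoderated statistic and leaving out each array. Alternatives added after the data were seen were those with the array sets, the fit without day 4 array 3 and day 8 array 1, and the fit of named genes without the other features.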

Results

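Ratios between EB and ES cells were compared day by day and between days. Values are log2 ratios as deposited, given as mean ± standard deviation over 3 arrays, with limma's adjusted p. A positive value is read as higher in EB. This direction is likely and not settled: it departs from the reading planned before the data were examined and opposes the sample titles and dye fields. If it is wrong, every higher and lower below is exchanged. Marker genes such as Zfp42, Nanog, Afp and Ttr decided this direction. The directions of pluripotency and endoderm genes given below therefore cannot count in its favour.

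After 4 days no feature passed the test against ES cells. Nanog (0.09 ± 0.26, n = 3, adjusted p = 0.923) and Pou5f1 (0.08 ± 0.14, adjusted p = 0.912), transcription factors that maintain the undifferentiated state, lay near 0. Their partner Sox2 did too (-0.12 ± 0.13, adjusted p = 0.814). Zfp42, a marker of undifferentiated ES cells, stood at -0.42 ± 0.15 (adjusted p = 0.295) and the Polycomb gene Phc1 at -0.51 ± 0.35 (adjusted p = 0.165). Ttr, the thyroid hormone carrier made by visceral endoderm and liver, was 0.38, 0.06 and 1.86 on the 3 arrays, and Afp, the fetal serum protein of the same tissues, averaged 0.30 ± 0.83 (adjusted p = 0.883).

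Of the 28 gene lists, glycolysis was called lower at day 4, with a list median of -0.22. By array the list median was -0.25, -0.54 and 0.04, so array 3 showed no decrease. The glycolysis list had adjusted p = 1.45e-05, and adjusted p = 0.991 with an estimated correlation. None of its 17 measured members passed over all features, and 3 were lower adjusted over the list alone. Pfkp, a phosphofructokinase, was at -0.41 ± 0.05 (adjusted p = 0.238). Ldhb, a lactate dehydrogenase subunit, was at -0.43 ± 0.20 (adjusted p = 0.206). Pdk1, which restrains pyruvate oxidation, was at -0.41 ± 0.32 (adjusted p = 0.284). With limma 0 features were called, 1081 had an unadjusted p under 0.05 where 534 were expected, and the smallest adjusted p was 0.0726. The day 4 arrays correlated with one another by -0.0158 to 0.205 across genes, less than those of the other days. In all 1 feature was called without array 1, 2 without array 2, and 87 with the array set as a term. Those 87, of which 22 were higher and 65 lower, include any calls of the 96 features without a gene that define the sets. The count was 119 after quantile normalization, 47 after scaling and 94 with array weights, so the absence of calls depended on the setting. The list test called 7 lists without day 4 array 2 in place of 1.

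By day 8, 7 of 32 genes of visceral endoderm and liver and 2 of 19 epithelial genes were called higher in EB, and 6 of 29 pluripotency genes lower. With an estimated correlation none of these 3 lists was called (adjusted p = 0.317, 0.377 and 0.365). S100g, a calcium-binding protein, rose by 2.29 ± 1.16 (n = 3, adjusted p = 0.00755). Spink1, a trypsin inhibitor, rose by 2.05 ± 0.83 (adjusted p = 0.0132) and Cyp26a1, which breaks down retinoic acid, by 1.64 ± 0.19 (adjusted p = 0.00349). Tinagl1, a matrix protein, was higher by 1.66 ± 0.53 (adjusted p = 0.00215) and the endoderm transcription factor Sox17 by 0.83 ± 0.23 (adjusted p = 0.00804). Zfp42 fell by 1.28 ± 0.35 (adjusted p = 0.00206), Nanog by 0.75 ± 0.23 (adjusted p = 0.0496) and Sox2 by 0.58 ± 0.35 (adjusted p = 0.0319). Pou5f1 was not called (-0.35 ± 0.34, adjusted p = 0.208).

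Visceral endoderm and liver genes were called higher at day 8 as a list, where 7 of 32 measured members rose, and 19 adjusted over the list alone. The endoderm list had adjusted p = 3.72e-11, and adjusted p = 0.317 with an estimated correlation. The day 8 arrays stood apart here: the list median was 0.0825, 0.407 and 0.867 on arrays 1 to 3. Afp was 0.0055, 2.42 and 3.01 (adjusted p = 0.0519) and Ttr -1.33, 2.54 and 2.98 (adjusted p = 0.236), so neither passed. Apoa1, the main protein of high-density lipoprotein, rose by 1.84 ± 1.36 (adjusted p = 0.0318), but without array 3 its value was 1.21 (adjusted p = 0.258). Epithelial genes were called higher with 2 of 19 members, the keratins Krt18 (1.27 ± 0.27) and Krt8 (0.81 ± 0.53), and 3 adjusted over the list alone. The epithelial list had adjusted p = 4.62e-04, and adjusted p = 0.377 with an estimated correlation. Basement membrane genes were higher as well, with 2 of 15 members called, the laminin chain Lamb1 (0.93 ± 0.24) and the collagen chain Col4a1 (0.65 ± 0.25), and 5 adjusted over the list alone. The Col4a1 mean averages probes that differed, at 0.17, 1.08 and 0.70. The basement membrane list had adjusted p = 0.00132, and adjusted p = 0.0986 with an estimated correlation. Of cell cycle inhibitors and p53 targets, 3 of 16 were higher: Ccng1 (0.57 ± 0.21), Trp53inp1 (0.56 ± 0.26) and Gadd45b (0.53 ± 0.14). The p53 target list had adjusted p = 5.15e-04, and adjusted p = 0.0844 with an estimated correlation, and 5 passed adjusted over the list alone.

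The pluripotency list was lower at day 8, with 6 of 29 members called lower, and 13 lower and 2 higher adjusted over the list alone. The pluripotency list had adjusted p = 3.10e-06, and adjusted p = 0.365 with an estimated correlation. Nr0b1, a nuclear receptor of ES cells, fell by 0.84 ± 0.75, with -0.43 and no call without array 3. The lists of nucleolus (adjusted p = 4.62e-04, 0 of 22 members called), cell cycle (adjusted p = 0.0323, 0 of 42) and chromatin (adjusted p = 0.0416, 0 of 23) were lower without a called member. With an estimated correlation the adjusted p was 0.365, 0.549 and 0.411. With fry these lists did not pass (adjusted p = 0.0885, 0.281 and 0.125). Pluripotency (fry adjusted p = 0.0572) and epithelium (0.0981) did not either. Endoderm (fry adjusted p = 0.0436), basement membrane (0.00432) and p53 targets (0.00345) did. The cell cycle and chromatin calls were lost without array 2, and those and the epithelial call without array 3. Of other genes, Stmn2, a tubulin-binding protein of neurons, fell by 1.13 ± 0.59 (adjusted p = 0.00879). The chemokine Ccl2 fell by 1.74 ± 0.64 (adjusted p = 0.022) and the membrane protein Tm4sf1 by 1.53 ± 0.85 (adjusted p = 0.0346). In all 244 features were called at day 8, 131 higher and 113 lower, and 35 of them by at least 1. The split turned to 153 higher and 197 lower with the replicate number as a block and to 210 and 244 with the array set as a term. All counts include any calls of the 96 features without a gene that define the sets. The turn with the set term may therefore not lie in genes. The count was 14 without day 8 array 2, 6 without array 3 and 1 in a fit of day 8 alone. It was 522 after quantile normalization, 608 after scaling and 999 with array weights. Arrays of other days moved it through the shared spread, to 161, 153 and 380 without day 15 arrays 1, 2 and 3 and 145 without day 21 array 2. Of 40 named calls only those of Tinagl1 and Zfp42 held without each of the 12 arrays.

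By day 15 genes of visceral endoderm and fetal liver were among those with the largest increases. Afp rose by 3.48 ± 0.14 (n = 3, adjusted p = 5.82e-04), Ttr by 3.37 ± 0.07 (adjusted p = 0.00486), and Trf, the iron carrier of serum, by 3.01 ± 0.59 (adjusted p = 8.01e-04). Genes of matrix and growth followed: Postn, a matrix protein of mesenchyme, rose by 2.46 ± 0.34 (adjusted p = 3.69e-07), and Igf2, an imprinted fetal growth factor, by 2.19 ± 0.21 (adjusted p = 1.55e-05). Zfp42 fell by 1.76 ± 0.33 (adjusted p = 1.55e-05). Dppa5a, an ES cell gene, fell by 1.66 ± 0.33 (adjusted p = 2.12e-05).

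Visceral endoderm and liver genes were called higher at day 15 with 18 of 32 members, and the list median was 0.70, 0.74 and 0.24 on arrays 1 to 3. The endoderm list had adjusted p = 4.06e-10, and adjusted p = 0.115 with an estimated correlation, and 20 higher and 2 lower passed adjusted over the list alone. Interstitial matrix genes were higher with 15 of 38 members and 1 lower, among them the fibrillar collagen chains Col1a2 (1.83 ± 0.66), Col3a1 (1.16 ± 0.02) and Col1a1 (1.07 ± 0.28). These means average probes that differed: those of Col3a1 were at 3.15, 0.25 and 0.08, and those of Col1a1 at 2.03, 0.34 and 0.83. The matrix list had adjusted p = 6.67e-09, and adjusted p = 0.1 with an estimated correlation, and 21 higher and 2 lower passed adjusted over the list alone. Imprinted genes were higher with 9 of 19 members, such as Dlk1 (1.64 ± 0.09), an inhibitor of fat cell formation, Mest (1.52 ± 0.28), a gene of growing mesoderm, and H19 (1.52 ± 0.44), an untranslated RNA. The imprinted list had adjusted p = 8.69e-09, and adjusted p = 0.1 with an estimated correlation, and 11 passed adjusted over the list alone. Of epithelial genes 6 of 19 were higher, with Krt18 at 1.96 ± 0.74 and Krt8 at 1.79 ± 0.22. The epithelial list had adjusted p = 1.98e-05, and adjusted p = 0.122 with an estimated correlation, and 6 passed adjusted over the list alone.

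Heart muscle genes were higher at day 15 with 6 of 26 members. The heart list had adjusted p = 5.99e-04, and adjusted p = 0.1 with an estimated correlation, and 8 passed adjusted over the list alone. The atrial myosin light chains Myl4 (1.59 ± 0.70, adjusted p = 0.00486) and Myl7 (1.36 ± 0.76, adjusted p = 0.00508) and cardiac actin Actc1 (0.74 ± 0.42, adjusted p = 0.00274) rose. Myh6, the atrial myosin heavy chain, was -0.08 ± 0.16 (adjusted p = 0.664). Smooth muscle genes were higher with 4 of 15 members, among them tropomyosin Tpm1 (0.91 ± 0.22) and smooth muscle actin Acta2 (0.79 ± 0.52). The smooth muscle list had adjusted p = 0.00405, and adjusted p = 0.115 with an estimated correlation, and 6 higher and 1 lower passed adjusted over the list alone. The embryonic globin Hba-x was higher by 1.29 ± 0.79 (adjusted p = 0.0106), while Hbb-bh1 stood at 0.17 ± 0.74 (adjusted p = 0.617). Lists of Wnt, TGF-beta and Notch signalling (6 of 27 members higher, adjusted p = 0.00136; 6 adjusted over the list alone), and primitive streak (5 of 25, adjusted p = 0.00701; 7 higher and 2 lower) were called higher too. So were p53 targets (4 of 16, adjusted p = 0.0122; 5), macrophage (3 higher and 1 lower of 23, adjusted p = 0.0154; 4 higher and 1 lower) and trophoblast (2 of 14, adjusted p = 0.0328; 5). With an estimated correlation the adjusted p of these 5 lists was 0.115, 0.115, 0.113, 0.282 and 0.115.

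The pluripotency list was lower at day 15 with 15 of 29 members, including Pou5f1 (-0.73 ± 0.39, adjusted p = 0.00778), Nanog (-0.73 ± 0.48, adjusted p = 0.0225) and Sox2 (-0.66 ± 0.17, adjusted p = 0.00537). The pluripotency list had adjusted p = 2.81e-12, and adjusted p = 0.1 with an estimated correlation, and 18 lower and 1 higher passed adjusted over the list alone. Cell cycle and DNA replication genes were lower with 12 of 42 members, such as the transcription factor Mybl2 (-1.01 ± 0.44), cyclin Ccne1 (-0.83 ± 0.23) and the replication origin protein Orc1 (-0.60 ± 0.02). Mki67, a marker of dividing cells, was 0.18 ± 0.18 (adjusted p = 0.188). The cell cycle list had adjusted p = 8.50e-10, and adjusted p = 0.115 with an estimated correlation, and 22 passed adjusted over the list alone. Glycolysis genes were lower with 7 of 17 members, among them Pfkp (-1.06 ± 0.16), Ldhb (-0.98 ± 0.16) and Pdk1 (-0.86 ± 0.08); Gapdh was -0.20 ± 0.37 (adjusted p = 0.422). The glycolysis list had adjusted p = 5.14e-06, and adjusted p = 0.115 with an estimated correlation, and 8 passed adjusted over the list alone. Nucleolus genes (6 of 22 lower, adjusted p = 6.81e-06; 14 adjusted over the list alone), and germ cell genes (4 of 9, adjusted p = 2.30e-04; 5) were lower. Called lower too were mitochondrial respiration (2 of 21, adjusted p = 8.98e-04; 6 lower and 1 higher), ribosomal proteins (0 of 29, adjusted p = 0.00405) and chromatin (5 lower and 1 higher of 23, adjusted p = 0.0445; 8 lower and 2 higher). With an estimated correlation the adjusted p of these 5 was 0.115, 0.115, 0.232, 0.516 and 0.327. Ribosomal proteins did not pass with fry either (adjusted p = 0.227). The ribosomal call rested on array 3: by array the list median was 0.02, -0.02 and -0.48, and without array 3 the list leaned higher (adjusted p = 0.917). Without array 3 the calls of respiration, macrophage and trophoblast were lost too, as was trophoblast without array 2 and chromatin without array 1.

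In all 1129 features were called at day 15, 605 higher and 524 lower, and 121 by at least 1. The split turned to 618 higher and 663 lower with the array set as a term and to 126 and 181 without array 1. It also turned to 111 and 124 without array 2 and to 117 and 142 in a fit of day 15 alone. Without array 3 it was 933 and 621. Counts with the set term include any calls of the 96 features without a gene that define the sets, so the turn with that term may not lie in genes. The count was 307 without day 15 array 1, 235 without array 2, 259 in a fit of day 15 alone, 1742 in the first array set and 3251 with array weights. Of 88 named calls 46 held without each of the 12 arrays, those of Afp, Ttr, Postn, Igf2, Zfp42 and Pou5f1 among them. Arrays of this day correlated by 0.413 to 0.833 across genes, and array 3 stood apart. Its list median was 0.14 for matrix (0.46 and 0.36 on arrays 1 and 2), 0.04 for smooth muscle (0.31 and 0.31), -0.25 for pluripotency (-0.49 and -0.69) and -0.54 for glycolysis (-0.23 and -0.22).

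**Figure D1:**
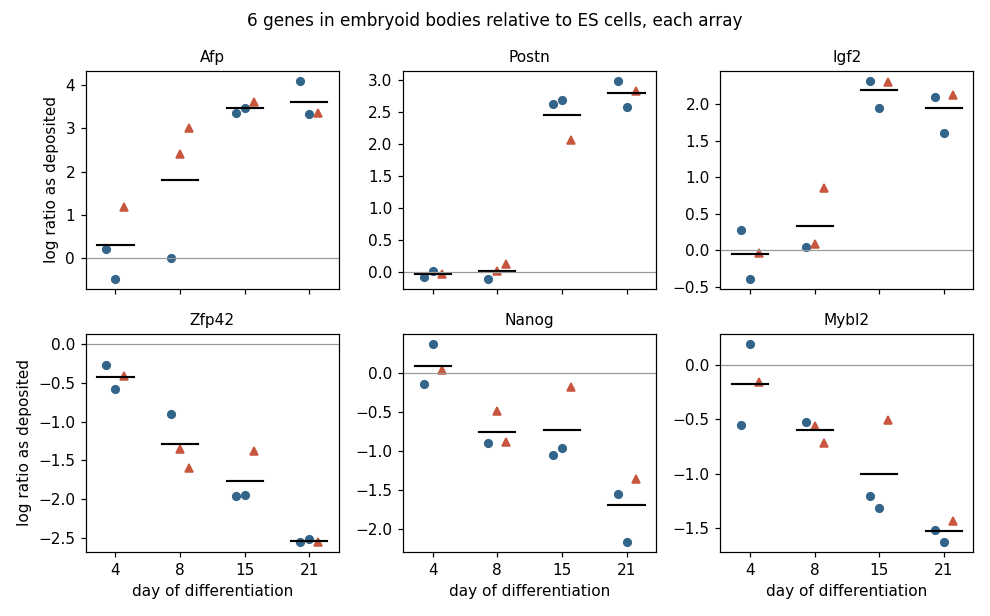
Log2 ratios (EB against ES as read here, vertical axis) of Afp, Postn, Igf2, Zfp42, Nanog and Mybl2 on each of the 12 arrays by day (horizontal axis), where blue circles are arrays of the first set, red triangles arrays of the second set and black bars day means. Afp has a day mean of 3.60 at day 21 and widely spread values at days 4 and 8, and the Zfp42 mean is -2.54 at day 21.

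At day 21, 20 of 32 genes of visceral endoderm and liver and 22 of 38 of interstitial matrix were called higher, and 20 of 29 pluripotency genes lower. With an estimated correlation none of these 3 lists was called (adjusted p = 0.094, 0.0558 and 0.0558). Afp was higher by 3.60 ± 0.44 (n = 3, adjusted p = 2.05e-04), Ttr by 3.26 ± 0.50 (adjusted p = 0.00336) and Postn by 2.80 ± 0.21 (adjusted p = 7.53e-08). Selenop, a selenium carrier made by liver, rose by 2.59 ± 0.37 (adjusted p = 1.68e-04). Zfp42 fell by 2.54 ± 0.02 (adjusted p = 7.62e-07), and Dppa5a by 2.14 ± 0.18 (adjusted p = 1.33e-06). Nr0b1 fell by 2.14 ± 0.17 (adjusted p = 3.56e-05) and Fbxo15, an ES cell F-box gene, by 2.08 ± 0.16 (adjusted p = 1.57e-05). The amino acid transporter Slc7a3 fell by 2.36 ± 1.86 (adjusted p = 0.00676), a value set by array 2 (-4.47), without which it was -1.30 (adjusted p = 0.0394).

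Of visceral endoderm and liver genes 20 of 32 were higher at day 21, with Apoa1 at 2.55 ± 0.38 and Sox17 at 0.57 ± 0.25. The endoderm list had adjusted p = 7.01e-13, and adjusted p = 0.094 with an estimated correlation, and 25 passed adjusted over the list alone. Of interstitial matrix genes 22 of 38 were higher and 1 lower, with Col1a2 at 1.94 ± 0.38, Col5a2 at 1.84 ± 0.24 and Col1a1 at 1.02 ± 0.20. The matrix list had adjusted p = 1.43e-12, and adjusted p = 0.0558 with an estimated correlation, and 24 higher and 1 lower passed adjusted over the list alone. Probes of 1 gene differed here: the 3 Col1a1 probes were at 2.15, 0.19 and 0.71, and those of Col3a1 at 2.85, 0.84 and 0.20. Imprinted genes were higher with 9 of 19 members, including Dlk1 (1.97 ± 0.21), Igf2 (1.95 ± 0.29) and H19 (1.48 ± 0.35). The imprinted list had adjusted p = 9.45e-09, and adjusted p = 0.0558 with an estimated correlation, and 9 passed adjusted over the list alone. Epithelial genes were higher with 8 of 19 members, with Krt8 at 1.67 ± 0.12 and Krt19 at 1.16 ± 0.06. The epithelial list had adjusted p = 6.25e-04, and adjusted p = 0.171 with an estimated correlation, and 9 passed adjusted over the list alone.

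Smooth muscle genes were higher at day 21 with 6 of 15 members, among them Acta2 (0.75 ± 0.26), Tagln (0.73 ± 0.37), an actin-binding protein, and the intermediate filament Vim (0.89 ± 0.03). The smooth muscle list had adjusted p = 0.00177, and adjusted p = 0.12 with an estimated correlation, and 6 passed adjusted over the list alone. Heart muscle genes were higher with 8 of 26 members. Actc1 was at 0.57 ± 0.11 and Myl4 at 1.29 ± 0.97, or 0.80 and not called (adjusted p = 0.0988) for Myl4 without array 1. Myh6 was not called (-0.11 ± 0.13, adjusted p = 0.467). The heart list had adjusted p = 0.00379, and adjusted p = 0.0558 with an estimated correlation, and 10 passed adjusted over the list alone. Endothelial genes were higher with 7 of 18 members, among them the adhesion molecule Icam2 (1.04 ± 0.53) and the growth factor receptor Kdr (0.41 ± 0.14). The endothelial list had adjusted p = 0.00498, and adjusted p = 0.0558 with an estimated correlation, and 7 passed adjusted over the list alone. Macrophage genes were higher with 8 of 23 members and 1 lower, with the complement gene C1qb at 0.84 ± 0.21 and the protease Ctss at 1.38 ± 0.94, or 0.90 without array 3. The macrophage list had adjusted p = 0.00231, and adjusted p = 0.171 with an estimated correlation, and 8 higher and 1 lower passed adjusted over the list alone. Signalling genes (8 of 27 higher and 1 lower, adjusted p = 0.00466; the same numbers adjusted over the list alone), and primitive streak genes (4 higher and 1 lower of 25, adjusted p = 0.0146; 9 higher and 1 lower) were higher. So were basement membrane genes (2 of 15, adjusted p = 0.0248; 2). The adjusted p of these 3 lists was 0.148, 0.152 and 0.127 with an estimated correlation. The primitive streak call was lost without array 3 and the basement membrane call without array 1.

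Of cell cycle and DNA replication genes 31 of 42 were lower at day 21. Mybl2 was at -1.53 ± 0.09, Orc1 at -1.03 ± 0.15, topoisomerase Top2a at -0.88 ± 0.19 and the mitotic kinase Cdk1 at -0.28 ± 0.08 (adjusted p = 0.0452), and Mki67, not called, was -0.17 ± 0.13 (adjusted p = 0.181). The cell cycle list had adjusted p = 4.36e-15, and adjusted p = 0.0558 with an estimated correlation, and 34 passed adjusted over the list alone. The pluripotency list was lower with 20 of 29 members. Nanog fell by 1.69 ± 0.42 (adjusted p = 7.91e-05), Sox2 by 1.01 ± 0.20 (adjusted p = 1.97e-04) and Pou5f1 by 0.74 ± 0.18 (adjusted p = 0.00412). The pluripotency list had adjusted p = 7.01e-13, and adjusted p = 0.0558 with an estimated correlation, and 21 lower and 1 higher passed adjusted over the list alone. Nucleolus genes were lower with 15 of 22 members, such as Dkc1 (-0.94 ± 0.48), which modifies ribosomal RNA, and Npm1 (-0.76 ± 0.13), which takes part in ribosome assembly. The nucleolus list had adjusted p = 1.58e-09, and adjusted p = 0.0558 with an estimated correlation, and 18 passed adjusted over the list alone. Mitochondrial respiration (8 of 21 lower, adjusted p = 1.92e-05; 15 adjusted over the list alone), and ribosomal proteins (6 of 29, adjusted p = 6.84e-04; 6) were lower. Lower too were chromatin (11 lower and 1 higher of 23, adjusted p = 8.03e-04; 12 lower and 1 higher), germ cell (4 of 9, adjusted p = 0.00466; 5) and glycolysis (4 of 17, adjusted p = 0.0103; 4). The adjusted p of these 5 was 0.15, 0.381, 0.148, 0.171 and 0.349 with an estimated correlation. Ribosomal proteins did not pass with fry either (adjusted p = 0.0783).

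Neural genes were not called as a list at day 21 (adjusted p = 0.291), with 3 of 35 higher and 3 lower. Stmn2 was at -1.77 ± 0.13 (adjusted p = 2.85e-05) and Tubb3, a neuronal tubulin, at 0.12 ± 0.19 (adjusted p = 0.389). Hox genes (0 of 26 called, adjusted p = 0.305), glia (0 of 13, adjusted p = 0.611) and erythroid genes (1 higher and 3 lower of 14, adjusted p = 0.988) were not called either. Nor were cartilage, bone and fat (2 higher and 3 lower of 20, adjusted p = 0.305), MHC and interferon genes (2 higher and 2 lower of 18, adjusted p = 0.641) and stress genes (6 higher and 3 lower of 22, adjusted p = 0.224). Trophoblast (2 of 14 higher, adjusted p = 0.0553) and p53 targets (4 higher and 2 lower of 16, adjusted p = 0.132) also missed the threshold. With fry the lists of trophoblast (adjusted p = 0.00519), p53 targets (adjusted p = 0.00372) and cartilage, bone and fat (adjusted p = 0.0496) did pass. Hbb-bh1 stood at 0.18 ± 0.06 (adjusted p = 0.532), Myc at 0.06 ± 0.23 (adjusted p = 0.8) and Gapdh at -0.20 ± 0.12 (adjusted p = 0.368). Actb was called higher at 0.36 ± 0.20 (adjusted p = 0.0483).

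In all 1999 features were called at day 21, 938 higher and 1061 lower, and 193 by at least 1. The split was 541 and 539 after quantile normalization and 1098 and 1058 in the first array set. The count was 753 without day 21 array 1, 872 without array 2, 1080 after quantile normalization and 993 after scaling. Of 108 named calls 70 held without each of the 12 arrays, not including those of Pou5f1, Sox17 and Acta2.

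**Figure D2:**
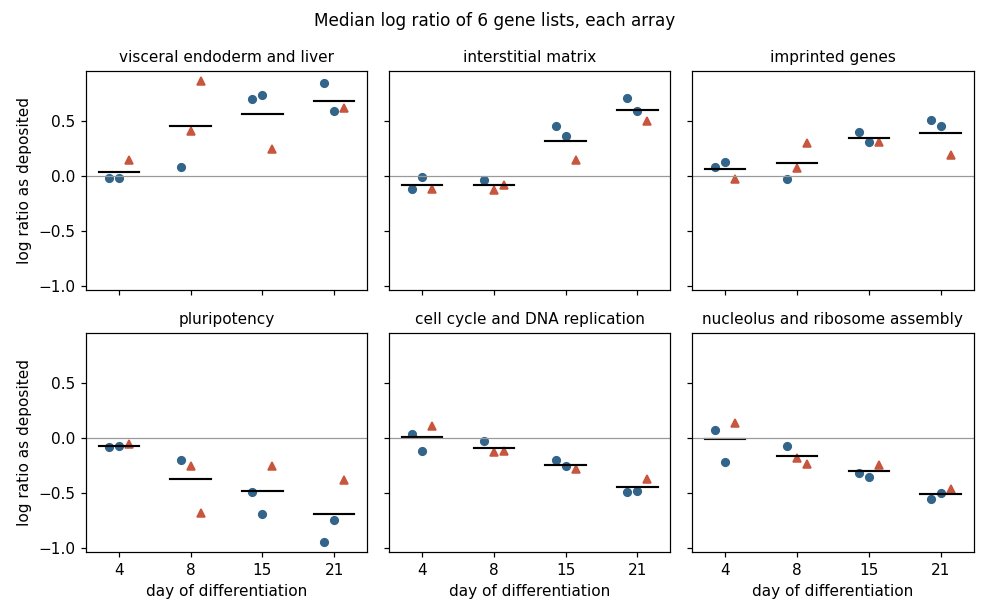
Median log2 ratio (vertical axis) of the measured genes of 6 gene lists (endoderm, matrix, imprinted, pluripotency, cell cycle, nucleolus) on each of the 12 arrays by day (horizontal axis), where blue circles are arrays of the first set, red triangles arrays of the second set and black bars day means. The visceral endoderm list goes from -0.0138, -0.0176 and 0.145 at day 4 to 0.846, 0.587 and 0.614 at day 21, and the pluripotency list reaches -0.942, -0.747 and -0.382.

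Days 15 and 21 shared 404 features higher than in ES cells, where 53.1 were expected of independent sets, and 387 lower features, where 52 were expected, with 0 in opposite directions. Days 8 and 21 shared 77 higher (11.5 expected) and 75 lower (11.2 expected). Part of the excess may come from the ES channel and the dyes, which every array had, since no array held ES RNA in both channels.

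Between days 4 and 21, 19 of 38 matrix, 10 of 32 visceral endoderm and 8 of 19 imprinted genes were called higher, and 10 of 29 pluripotency and 16 of 42 cell cycle genes lower. With an estimated correlation none of these 5 lists was called. The ES channel drops out of this difference only if its RNA was the same on all arrays, which was not tested. Postn was higher at day 21 by 2.83 (adjusted p = 4.34e-06, n = 3 and 3), Dlk1 by 2.01 (adjusted p = 4.70e-05), and Afp by 3.29 (adjusted p = 0.00951). Ttr was not called (2.49, adjusted p = 0.121). Zfp42 fell by 2.12 (adjusted p = 1.23e-04), Dppa5a by 1.95 (adjusted p = 2.22e-04), Nanog by 1.78 (adjusted p = 0.00242) and Pou5f1 by 0.82 (adjusted p = 0.0348). Of interstitial matrix genes 19 of 38 were higher. The matrix list had adjusted p = 1.43e-15, and adjusted p = 0.0545 with an estimated correlation, and 22 higher and 1 lower passed adjusted over the list alone. Of cell cycle genes 16 of 42 were lower (adjusted p = 7.63e-17, and adjusted p = 0.0545 with an estimated correlation; 25 adjusted over the list alone). Of pluripotency genes 10 of 29 were lower (adjusted p = 8.62e-13, and adjusted p = 0.0568 with an estimated correlation; 15 adjusted over the list alone). Visceral endoderm genes were higher with 10 of 32 members (adjusted p = 8.77e-13, and adjusted p = 0.0882 with an estimated correlation; 18 adjusted over the list alone). Imprinted genes were higher with 8 of 19 (adjusted p = 4.07e-09, and adjusted p = 0.0545 with an estimated correlation; 9 adjusted over the list alone). In all 18 lists were called, 11 higher and 7 lower, of which 0 passed with an estimated correlation (smallest adjusted p = 0.0545). Features called were 624, 280 higher and 344 lower. The split turned to 497 higher and 332 lower in the first array set, to 217 and 178 in a fit of the 2 days alone and to 241 and 225 without day 4 array 3. The count was 266 without day 4 array 1, 223 without day 21 array 1, 264 without day 21 array 2, 368 after quantile normalization, 315 after scaling and 1343 with array weights.

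Between days 8 and 15 limma called 19 features, against 0 between days 4 and 8 and 1 between days 15 and 21. Postn rose by 2.44 (from 0.01 ± 0.11 to 2.46 ± 0.34, n = 3 and 3, adjusted p = 2.45e-05), and Col1a2 by 2.39 (adjusted p = 0.00838). Igf2 rose by 1.86 (adjusted p = 0.00567), Dlk1 by 1.47 (adjusted p = 0.00162) and Col3a1, as a mean of probes that differed, by 1.32 (adjusted p = 8.68e-05). Sycp3, a protein of meiotic chromosomes, fell by 1.29 (adjusted p = 0.0325), Upp1, a uridine phosphorylase, by 1.29 (adjusted p = 0.0336) and Ldhb by 0.92 (adjusted p = 0.0312). Of the 19 calls 14 were higher and 5 lower; the split was 15 and 2 after quantile normalization and 11 and 2 after scaling. The count was 9 without day 8 array 1, 7 without day 8 array 2, 4 without day 15 array 1, 8 without day 15 array 2, 126 without day 15 array 3 and 12 without day 21 array 2. Without day 4 array 3 and day 8 array 1 the 3 neighbouring comparisons had 35, 6 and 0 calls, and with array weights 78, 582 and 1, so their order depended on the arrays. The calls of Postn, Dlk1 and Col3a1 held without each array.

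Between days 4 and 8 limma called 0 features (746 at an unadjusted p under 0.05, smallest adjusted p = 0.193). Afp differed by 1.51 (adjusted p = 0.649), Zfp42 by -0.86 (adjusted p = 0.234) and Sox17 by 0.79 (adjusted p = 0.231). Between days 15 and 21 only Npff, which encodes a neuropeptide precursor, was called, rising by 0.83 (from 0.37 ± 0.10 to 1.19 ± 0.07, adjusted p = 0.0208). That call was lost without any 1 of 8 arrays (day 4 array 1, day 8 array 3, the 3 of day 15 and the 3 of day 21). It was also lost with the replicate number as a block (adjusted p = 0.0882), where same-number arrays of these days correlated by 0.237, 0.151 and 0.389, and after quantile normalization (adjusted p = 0.345) and scaling (adjusted p = 0.242). Across all days the F-test called 310 features. That count was 120 without day 4 array 1, 184 without day 4 array 3, 143 without day 8 array 2, 170, 160 and 543 without day 15 arrays 1, 2 and 3, and 101 and 108 without day 21 arrays 1 and 2. It was 203 after quantile normalization, 163 after scaling and 1416 with array weights.

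**Figure D3:**
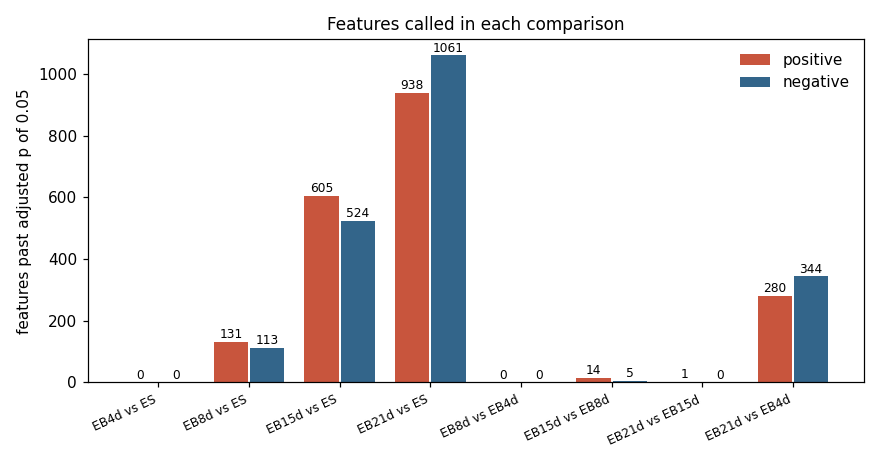
Number of features called at an adjusted p of 0.05 (vertical axis) in each comparison (horizontal axis), red for positive and blue for negative values. The calls against ES go from 0 at day 4 to 244, 1129 and 1999 at days 8, 15 and 21.

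**Figure D4:**
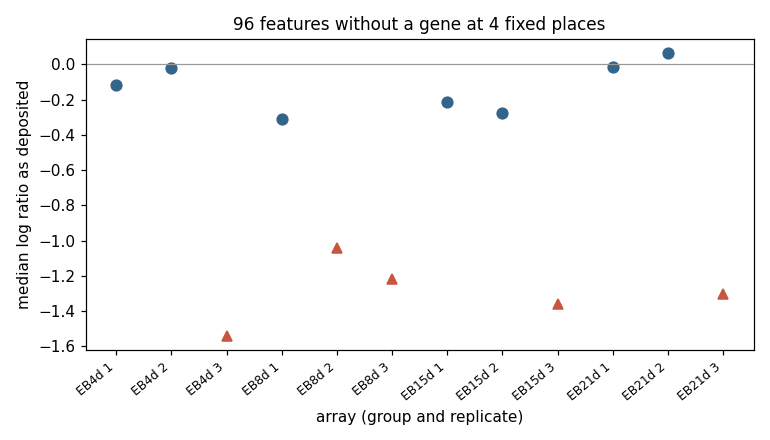
Median log2 ratio (vertical axis) of 96 features without a gene at 4 positions of every block of 480 features, on each of the 12 arrays (horizontal axis). The 5 arrays of the second set (red triangles) lie between -1.54 and -1.04 and the 7 of the first set (blue circles) between -0.31 and 0.064.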

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

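The tests of the day of differentiation, of exchanged arrays and the array set for the endoderm genes, and of a dye effect were chosen only after the result was seen. Differences between days stood out in 3 comparisons: 19 features between days 8 and 15, 1 between days 15 and 21 and 624 between days 4 and 21. The 6 arrays of each such comparison allow 10 splits, too few to judge chance. The real and the highest other count were 0 and 4 between days 4 and 8 (10 splits reached the real count), 19 and 3 between days 8 and 15 (1 split), 1 and 0 between days 15 and 21 (1 split), 624 and 0 between days 4 and 21 (1 split), and for gene lists between days 4 and 21, 18 and 12 (1 split). For the F-test across days the real grouping had 310 calls and the others at most 37. Only the real grouping reached its count, and 1 of 100 splits was the lowest share possible. Random groupings of these arrays thus seldom gave as many calls. The splits treat arrays as independent, although those of a day may be technical.

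Genes called in opposite directions on different days were Sycp3 (0.85 at day 8 and -1.07 at day 21, F-test adjusted p = 0.00186), Tagln (-0.86 and 0.73, adjusted p = 0.00234), Nfib (-0.47 and 0.59, adjusted p = 0.00189; chosen after its values were seen) and Ccng1 (0.57 and -0.40, adjusted p = 0.0188). Bmp4 was at -0.58 at day 8 and 0.64 at day 15 (adjusted p = 0.00755).

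A signal also stood in features that were tested but belong to no gene or gene list. These 96 features, at fixed positions, had a median of -1.3 over the 5 arrays of the second set. A region of the array was tested through 197 annotated features within 3 feature numbers. Their gap between the sets was -0.0299, against -1.1 for the features themselves. This argues against an effect shared by neighbouring feature numbers. The layout of the array was not given, so the test cannot exclude a region in space. The day of differentiation was argued against by a range within 1 day of 1.52, with day means that span 0.439. With the set as a term 2126 features were called at day 21, of which 1877 were among the 1999. This count cannot exclude the array set as a source of those calls. The term leaves the mean of the 2 sets in each ratio against ES, and the 96 features were themselves tested. What the features hold, and whether the sets are batches of labelling or of arrays, stays open.

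Visceral endoderm genes stood apart within days 4 and 8: day 4 array 3 had a list median of 0.145 against -0.0138 and -0.0176, and day 8 array 1 had 0.0825 against 0.407 and 0.867. An exchange of day 4 array 3 with day 8 array 1 cannot be told apart. Pluripotency genes were lower on day 8 array 1 than on day 4 array 3 (median difference -0.177, 20 of 29 genes). A two-sided sign-flip permutation of the mean difference over genes gave p = 0.0106, genes not being independent. But arrays of 1 day differed in the median by up to 0.482. The array set cannot be told apart either. Over days 15 and 21 the second-set arrays were lower in endoderm genes (median difference -0.277, 25 of 32 genes), but with 1 such array a day. The permutation of the mean difference over genes gave p = 1.10e-04. At day 21 that array (0.614) lay between the others (0.587 and 0.846). A candidate explanation is that cultures of the same day may differ in how much endoderm they formed, which was not tested.

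Of 14 genes typical of fibroblasts, picked after their values were seen, 5 were called lower in EB than in ES cells at day 8 and 9 did not pass. Among the 5 were Ccl2 (-1.74), Tm4sf1 (-1.53) and Col8a1 (-1.15). RNA of fibroblasts, which can serve as feeder cells, in the ES channel may be a source, although the labels give gelatin; 38 other fibroblast markers had a median of -0.0331 (95% bootstrap interval -0.213 to 0.0286, percentile 11.2 of 10000 random lists), 23 were below 0, 0 were called lower and 2 higher, so that this cannot be told apart, since the interval is wide and 13 of them are matrix genes that EB cells also express. A dye effect of the 14 genes would be alike on all days. Their median per array ran from -0.0292 (day 4 array 2) to -1.41 (day 8 array 3), wider than such an offset alone would give. It also spread within days, from -0.339 to -1.41 at day 8. It did not pass a test between days (exact permutation p = 0.523 over 15400 splits), with 3 arrays a day and genes picked at day 8. A dye effect as part of the pattern therefore cannot be told apart. No biological explanation was tested.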

How the results depend on the processing

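The settings with array sets, without day 4 array 3 and day 8 array 1, and with named genes alone were chosen only after the result was seen. Counts stand in the order EB4d, EB8d, EB15d and EB21d against ES, then EB8d against EB4d, EB15d against EB8d, EB21d against EB15d, EB21d against EB4d, and the F-test; as reported they were 0, 244, 1129, 1999, 0, 19, 1, 624 and 310. Quantile normalization gave 119, 522, 776, 1080, 2, 17, 0, 368 and 203; scaling gave 47, 608, 904, 993, 0, 13, 0, 315 and 163. Array weights gave 94, 999, 3251, 2622, 78, 582, 1, 1343 and 1416. A fit of the compared groups alone gave 0, 1, 259, 1390, 0, 5, 0 and 395, having fewer degrees of freedom, and an unmoderated statistic 6, 17, 718, 1539, 0, 6, 2 and 346. The array set as a term gave 87, 454, 1281, 2126, 0, 21, 1, 742 and 407; the first set alone 0, 10, 1742, 2156, 0, 159, 0, 829 and 545; the second 85, 259, 115, 226, 0, 0, 0, 10 and 0. A day with 1 array (day 8 in the first set, days 4, 15 and 21 in the second) was assumed to vary like the others, and the second set left 1 residual degree of freedom, so its counts say little. Without day 4 array 3 and day 8 array 1 there were 15, 222, 1058, 1883, 35, 6, 0, 494 and 174. Except where construction shows it, the cause was not tested. Counts with the array set as a term include any calls of the 96 features that define the sets. Centring, each probe on its own and named genes alone left each count within 1.5 times its reported value. The replicate number as a block gave 0, 350, 1243, 2036, 0, 16, 0, 614 and 270. The 18 same-number pairs correlated by -0.14 to 0.389, 8 of them over 0.1, and the numbers were not taken as pairs. Yet 10 of 12 arrays correlated best with an array of their own number, so pairing is not excluded. Arrays numbered 3 were all in the second set and those numbered 1 all in the first, and the 96 features entered these correlations. Pairing and array set therefore cannot be told apart here.

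Leaving out 1 array gave, in that order, 0 to 2, 6 to 380, 235 to 1554, 753 to 2221, 0 to 6, 4 to 126, 0 to 1, 223 to 773 and 101 to 543. Called lists (days 4, 8, 15 and 21 against ES, then day 21 against day 4) were 1, 8, 19, 19 and 18, and 1 to 7, 5 to 10, 15 to 19, 18 to 20 and 15 to 18 without 1 array; with an estimated correlation they were 0, 0, 0, 0 and 0, with fry 0, 3, 20, 21 and 16, and in the first array set 1, 2, 15, 16 and 16. Among named genes, 8121 leave-one-out results kept their side of the threshold, 531 lost a call, 120 gained one and 0 reversed. Reversed were Fos (-0.033) and Lmo2 (-0.0067) at day 15 in the second array set, and 1 Col4a1 probe between days 4 and 21 (-0.0095); the cause was not tested. Of called lists the ribosomal proteins of day 15 reversed without day 15 array 3 (adjusted p = 0.917) and in the first array set (adjusted p = 0.955). Turning the sign exchanged higher and lower (938 and 1061 at day 21 became 1061 and 938), moved no count and negates each named value. Features with values on all 12 arrays were not run as a setting, since 0 values were missing. Signal over background was not analysed here.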

Other observations

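The genes of this part were picked for description after their values were seen, with no further test. The metallothioneins Mt1 and Mt2, which bind metals, were higher at day 21 by 1.09 ± 0.12 (n = 3, adjusted p = 0.00108) and 1.10 ± 0.24 (adjusted p = 0.00652). Nrp1, a receptor of vessels and nerves, went from -0.14 ± 0.21 at day 4 (adjusted p = 0.935) to 2.37 ± 0.26 at day 21 (adjusted p = 4.20e-04). Fabp4, a lipid carrier of fat cells and macrophages, was higher at day 21 by 1.32 ± 0.49 (adjusted p = 0.00119), and B2m, the light chain of MHC class I, by 1.03 ± 0.14 (adjusted p = 0.00443). The inhibitors of DNA binding Id2 and Id3 were higher at day 15 by 1.05 ± 0.21 (adjusted p = 8.06e-04) and 1.19 ± 0.25 (adjusted p = 0.00158).

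Of enzymes, Upp1, which splits uridine, was at -0.24 ± 0.07 at day 4 (adjusted p = 0.641) and fell by 1.85 ± 0.17 at day 21 (adjusted p = 1.57e-05), and Prps1, which makes the sugar phosphate of nucleotides, fell by 1.31 ± 0.09 (adjusted p = 8.42e-06). Pycard, an adaptor of inflammasomes, fell by 1.92 ± 0.24 at day 21 (adjusted p = 1.27e-04), and the calcium-binding protein S100a4 by 1.72 ± 0.21 (adjusted p = 0.00622). The cyclin-dependent kinase inhibitors Cdkn1a and Cdkn1c were higher at day 15 by 0.91 ± 0.29 (adjusted p = 6.53e-04) and 0.88 ± 0.17 (adjusted p = 6.50e-04).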
